A study of Drosophila melanogaster with 3 samples.

How the data were processed

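The series measured where a tagged form of Grauzone (gene grau) was found on chromatin in whole fruit fly embryos by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA bound by a protein is pulled down with an antibody and sequenced. The flies carried grau fused to green fluorescent protein (GFP) and the antibody was raised against GFP, per the labels. Embryos of both sexes were pooled at 0 to 24 hours of age, and DNA fragments of 200 to 800 bp were kept. The labels gave 1 group with 3 biological replicates and a control experiment. No control list was analysed here, so values have no background measured in the same way beside them.

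The authors deposited a peak list for each replicate, a list called on the pooled alignments and a reproducible list, which the accompanying file descriptions name as the optimal set thresholded by irreproducible discovery rate (IDR). Coordinates were on dm6, per the file headers and labels. The aligner, the peak caller and the IDR threshold were not given in the sources used here. Read depth was not used here, and signal tracks named in the descriptions were not analysed here. Each deposited list gives a signal value per peak, whose scale was not stated, and a −log10 q-value. The signal was used to rank peaks within a list and to compare medians at promoters with the rest. For peaks matched across replicate lists, it was divided by each list's median and averaged. All 9624 peaks of the reproducible list shared 1 q-value, so q could not rank them. A further deposited column gives the distance of the point source, the most enriched base, from the start of the peak. The 3 replicate lists and the pooled list each held exactly 30000 peaks. The reproducible list held the 9624 pooled peaks with the highest signal, at identical point sources, so results from it are pooled values with no spread of their own. To give a spread, each share was also computed in the 9624 strongest peaks of each replicate, as mean ± SD over 3 replicates.

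Chromosome lengths and annotation came from the dm6 assembly and Ensembl release 115, both on the same build, and 0 peaks fell outside the reference chromosomes. Transposable elements and pseudogenes were left out of the 23358 transcription starts. A promoter peak has its point source within 500 bp of a start. Other point sources were assigned in the order 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic. Random placement used 1000 circular shifts of the peaks along each chromosome, which keep their spacing. The smallest p these shifts can give is 0.001 one-sided and 0.002 two-sided. Peaks matched where point sources lay within 100 bp.

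Gene lists were compared with all other genes of the same biotype by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 16 lists. Where lists were split into divergent and other genes, the adjustment ran over both parts of all lists together, which is more tests. The tRNA and snRNA lists held every gene of their biotype and were compared with shifts only. Symbols missing from the annotation were dropped. Motifs, 11 in all, were counted on either strand in 101 bp windows at the point source and in flanking windows centred 500 bp away on alternating sides, with an exact binomial test on discordant peaks. An 8-base word was searched for among words in at least 2% of peaks, on chromosome 2, and tested on chromosomes 3, 4 and X. Signal at promoters was compared by 100000 permutations of the class over peaks. Intervals are 95% Wilson intervals for shares of peaks and 95% Clopper-Pearson intervals for gene lists. They cover counting error only, since neighbouring peaks and genes are not independent. A divergent promoter is a protein-coding gene's start within 500 bp of the start of a gene on the other strand.

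The genes named in the text followed a rule. It took cort and grau, the genes with a start within 500 bp of the 20 reproducible promoter peaks with the highest signal, the 5 highest peaks farther from any start, and up to 4 members of each list with the highest promoter peak. The rule can also be read as the 20 highest peaks anywhere, of which fewer lie at promoters. It was applied to the 20 highest at promoters. Examples from it are given rather than every gene. The tests, gene lists, motifs and the rule were fixed before the data were examined. GC content, values by rank bin, the strongest peaks against a whole list, the position of promoter peaks and the spread over the replicates' own peaks were added later. Tests ran in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9. The functions were tested on simulated data. In 20 simulated peak sets with no effect, 1 of 320 gene list tests and 0 of 140 feature tests passed the threshold, and a planted motif excess of 5 percentage points was recovered as 5.00. The sets with no effect had peaks at uniform random places. The rate of false calls with peaks concentrated at promoters was not checked. Alternatives covered other peak sets, leaving out each replicate, other distances, other matches, other random placements and other motif backgrounds. Except for replicate support, leaving out a replicate meant a new set of peaks. It held the 9624 highest by mean rank among peaks matched within 100 bp in the remaining replicate lists. This set is built unlike the reproducible list, so a change in it cannot be put down to the replicate left out alone. The set of peaks matched in all 3 lists was built the same way.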

Results

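The data were peak lists from ChIP-seq of GFP-tagged Grauzone in whole fruit fly embryos, in 1 group with 3 biological replicates. Grauzone is a zinc finger protein of the ZAD family, known as an activator of cortex (cort), which is needed to complete meiosis in the egg. Each replicate's list held 30000 peaks, and the reproducible list held 9624 peaks with a median width of 360 bp. With 1 group, the comparisons are between replicates and between parts of the genome. Signal values are the authors' own. They are compared only within a list, or within a set of matched peaks after scaling to each list's median. The sequencing depth behind each peak is unknown here.

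The strongest places were shared between replicates more often than the rest. Of the 1000 strongest peaks of a replicate, a mean of 84.0% ± 4.95 (SD over 3 pairs of replicates) had a peak within 100 bp among the 1000 strongest of another, from 79.0% for replicates 1 and 3 to 88.9% for replicates 1 and 2, against 0.149% after shifting. In the whole list of another replicate the share was 99.1% ± 0.225 (SD over 3 pairs), against 4.56% after shifting. Among the whole lists the share was 55.4% ± 3.42 (SD over 3 pairs), against 4.54% after shifting. Replicates 1 and 2 matched at 59.3%, replicates 1 and 3 at 52.8% and replicates 2 and 3 at 54.2% (one-sided permutation p = 0.001 for each pair, the smallest the shifts allow). The match fell with rank, from 97.47% in ranks 1 to 3000 to 19.98% in ranks 27001 to 30000. Between 54.3% and 60.9% of each replicate's peaks had a q-value of 0.01 or less. Across matched peaks, the signal ranks correlated with a mean Spearman rho of 0.85 ± 0.0145 (SD over 3 pairs), and among the 1000 strongest with 0.81 ± 0.0974. This correlation is across peaks, which are not independent replicates.

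**Figure D1:**
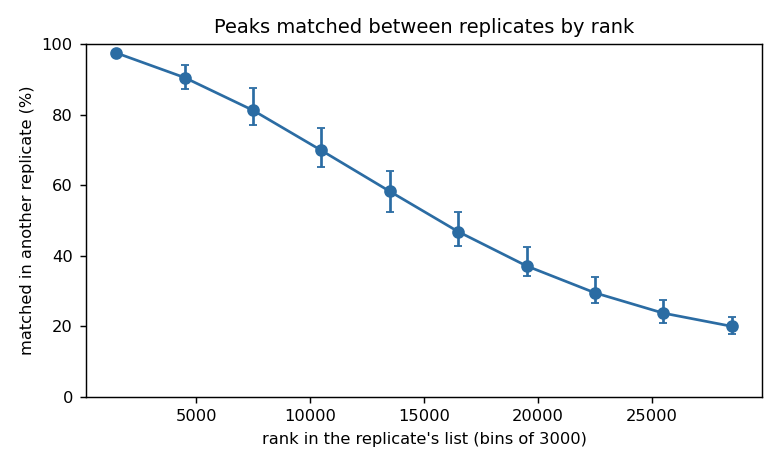
Share of peaks matched within 100 bp in another replicate's list (y axis, %) by rank in bins of 3000 (x axis), as means over the 6 ordered pairs of replicates with bars from the lowest to the highest pair. The share falls from 97.47% to 19.98%.

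Most reproducible peaks were present in each replicate. Of the 9624 peaks, 95.8% were matched in replicate 1, 96.6% in replicate 2 and 95.6% in replicate 3, a mean of 96.0% ± 0.519 (SD, n = 3). All 3 lists held 8560 of them, or 88.9% (95% interval 88.3% to 89.6%). The list was taken from the replicates' own pooled alignments and selected for reproducibility, so a high share was built in, and the 1.69% after shifting is no test of it. A further 967 were in exactly 2 lists, 93 in 1 and 4 in none.

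Several of the strongest reproducible peaks lay between genes that read away from each other. The highest of all lay in an intron of larp, which encodes a La-related RNA-binding protein, on 3R from 28326044 to 28327599, with a signal of 30239.7, 338 bp from a start. The next, on 2L from 13834853 to 13835992 with a signal of 29361.7, lay between CenG1A, an Arf GTPase-activating protein, and mRpS23, a mitochondrial ribosomal protein gene. Others lay between Dad1, an oligosaccharyltransferase subunit, and CG13384 (2L, 8383838 to 8384737, signal 16305.8), and between Pex6, needed to form peroxisomes, and Taf5, a subunit of the general transcription factor TFIID (2R, 10879392 to 10880244, signal 15815.3). The pairs CG2698 and Kmn2, a kinetochore gene, and CG13933 and PolD2, a DNA polymerase delta subunit, shared peaks with signals of 14309.9 and 13757.5. Art3 and mRpS10, Pyroxd1 and CG10747, SMC6 and CG6204, and Rtel1 and IntS6 also shared a peak each among the 20 highest at promoters. Vti1b and Vha100-2, overlapping genes that act in vesicle fusion and acidification, shared a peak in a 5′ UTR (signal 13019.4). A peak at rank 28 covered several short transcripts of the mod(mdg4) locus, which encodes chromatin proteins through trans-splicing. In each replicate the peaks of larp and of the CenG1A and mRpS23 pair ranked 1 or 2.

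Of the 5 highest peaks farther than 500 bp from any start, a pair lay close together on 3R. One was in an intron of tara, a regulator of the cell cycle, from 16235257 to 16237458 (signal 24306.7), and the other lay between 2 long noncoding RNA genes, CR45641 and CR45643, from 16221421 to 16222915 (signal 16760.0). The remaining peaks were in introns of KCNQ, a potassium channel gene (2R, 10159081 to 10160567), and CHES-1-like, a forkhead gene (X, 7706316 to 7707744), and in the gap between blw and CycB, which encodes cyclin B (2R, 22802520 to 22803421).

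Cort, the known target, had a reproducible peak 17 bp from its start, on 2L from 6676582 to 6676726, in the 3′ UTR of the overlapping gene Nse1. Its signal of 290.7 ranked 7107 of 9624. Of all protein-coding genes, 4476 of 13945, or 32.1%, had a promoter peak, so a peak at this start does not single out cort. The cort peak ranked 7870 in replicate 1 and 7560 in replicate 2, and in replicate 3 the nearest peak was 2807 bp away. In peaks matched without replicate 1 or without replicate 2, the nearest lay 2782 bp and 2758 bp from the cort start. Grau had no reproducible peak at its start, the nearest being 5630 bp away. Replicates 1 and 2 had peaks 6 bp and 14 bp from the grau start, at ranks 3630 and 3715, which the pooled list did not hold, and the nearest peak of replicate 3 was 5635 bp away. In peaks matched without replicate 3, one lay 4 bp from the grau start.

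Reproducible peaks were concentrated at promoters and almost absent from coding sequence. Promoters held 4130 point sources, or 42.9% (95% interval 41.9% to 43.9%), against 13.4% after shifting (two-sided permutation p = 0.002). In the replicates' own strongest peaks the share was 44.2% ± 3.35 (SD, n = 3). Coding exons held 0.333% against 13.7% after shifting, 3′ UTRs 1.07% against 4.45%, 5′ UTRs 0.468% against 0.784% and intergenic sequence 15.6% against 27.5% (adjusted permutation p = 0.0028 for each). Introns held 38.6% against 39.5% (adjusted permutation p = 0.288), and were above their shifts without replicate 1 (40.3%) or replicate 2 (40.004%), also without passing the test. Peaks matched in all 3 lists turned the same way (40.6%), so the turn cannot be put down to leaving out a replicate. Other exons held 1.02% against 0.764% (adjusted permutation p = 0.035), a call that was lost without replicate 1 (1.01%) or replicate 3 (0.966%). Promoters held 55.3% of the 1000 strongest peaks and 36.7% of the weakest, ranks 9001 to 9624. In between, from rank 2001 to 9000, the share stayed between 39.7% and 42.9% in sets of 1000. No spread over replicates was computed for these shares by rank. Promoter point sources had a median position of -102 bp relative to the nearest start, and 78.7% were upstream of it (95% interval 77.5% to 80.0%). A point source between starts that read away from each other is upstream of either. Part of this share can therefore follow from the arrangement of genes, and no shifted share was computed for it.

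**Figure D2:**
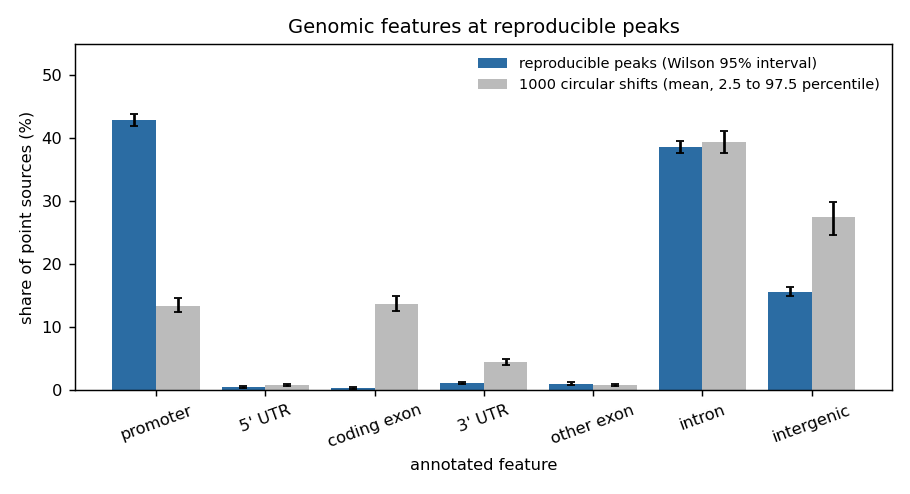
Share of reproducible point sources in each annotated feature (y axis, %), with Wilson 95% intervals, beside the mean of 1000 circular shifts with its central 95% range. Promoters stand at 42.9% against 13.4%, and coding exons at 0.333% against 13.7%.

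Protein-coding genes with a divergent promoter had a peak near a start far more often than other protein-coding genes. Of 4270 protein-coding genes with a start near that of a gene on the other strand, 2339 had a promoter peak, or 54.8% (95% interval 53.3% to 56.3%), against 2137 of 9675 other genes, or 22.1% (two-sided Fisher's exact test, p = 1.48e-307). In the replicates' own peaks the shares were 56.2% ± 2.34 and 22.4% ± 1.57 (SD, n = 3). A peak near 1 start of a pair can count for both genes, so some of this difference can follow from the definition. The test also treats paired genes as independent. With each pair counted once the difference was 30.9 percentage points (two-sided Fisher's exact test, p = 8.08e-182), but a neighbour's peak could still count. How much of the difference this gives was not tested. Promoter peaks had a median signal of 468.7 against 420.6 for the rest, a ratio of 1.11 (two-sided permutation p = 1e-05, the smallest the permutations allow). The ratio was 1.11 ± 0.176 in the replicates and ranged from 0.977 to 1.31, so this difference did not exceed the spread between replicates. It was not past the threshold without replicate 3 or with a promoter distance of 250 bp, where the ratio was 1.04 in both cases.

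Peak density differed little between the large arms and was low on chromosome 4. The X carried 80.7 peaks per Mb and the 4 large autosome arms 70.6, a ratio of 1.14 (two-sided exact binomial test, p = 2.53e-07). In the replicates the ratio was 1.11 ± 0.0439 (SD, n = 3). Males have 1 X, so in pooled sexes this ratio is not a test of binding. Chromosome 4, which is largely heterochromatic, carried 17.8 peaks per Mb with 24 peaks, and Y carried 0.

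Of the lists, cytosolic ribosomal protein genes had promoter peaks most often, with 74 of 86, or 86.0% (95% interval 76.9% to 92.6%), against 31.8% of other protein-coding genes (adjusted Fisher's exact p = 2.69e-24). In the replicates' own peaks the share was 87.6% ± 0.671 (SD, n = 3). The highest peaks of these genes were at RpL34b (signal 2686.5), RpL23 (2068.1), RpS27 (2012.5) and RpL14 (1720.2), at ranks 497 to 983. Proteasome subunit genes had 19 of 32, or 59.4% (adjusted Fisher's exact p = 0.00494), led by Rpn3, Rpn13, Rpn11 and Rpn6. That call was lost in the stronger of 2 equal sets of peaks, where the difference was 9.06 percentage points against 27.3. The 21 divergent and the 11 other genes taken separately did not pass either, at differences of 11.9 and 23.4 percentage points (adjusted Fisher's exact p = 0.561 and 0.185). Those parts hold fewer genes and were adjusted over more tests, so this does not show that the difference is absent from them. Aminoacyl-tRNA synthetase genes, with 16 of 33 or 48.5%, respiratory chain genes, with 34 of 84 or 40.5%, and heat shock genes, with 10 of 21 or 47.6%, did not pass the test (adjusted Fisher's exact p = 0.0959, 0.148 and 0.182). All 3 passed it where genes that share a peak were merged, with differences of 23.3, 15.3 and 22.4 percentage points. Only genes with a peak can be merged. Merging therefore lowers the share of other genes by construction, and these gains are no evidence about the lists. The respiratory chain list also passed without replicate 2 (11.03) and without replicate 3 (16.9). It passed in peaks matched in all 3 lists too, so these passes cannot be put down to leaving out a replicate. Without replicate 2 the synthetase difference went from 16.4 to 8.72 and the heat shock difference from 15.5 to 7.41. Hsp27, a small heat shock protein gene, had a peak with a signal of 3481.3, and GluProRS, a tRNA synthetase gene, one of 3163.6.

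The meiosis and egg activation, ZAD zinc finger and insulator lists were above other genes in the main comparison, with calls that several alternatives ended. These lists do not stand out for what is known of Grauzone. Cytosolic ribosomal protein genes had a higher share (86.0%), and the germline and piRNA pathway list was below other genes (26.5% against 32.1%). In the meiosis and egg activation list, 21 of 37 genes, or 56.8%, had a promoter peak, against 32.0% of other genes (adjusted Fisher's exact p = 0.00516). Besides cort, its members with the highest peaks were smg, a translational repressor of maternal mRNA (signal 2057.8), Cdk1 (1068.1), and the kinases aurA (893.5) and aurB (821.4). The difference of 24.7 percentage points was not past the threshold with a distance of 250 bp (14.3), in the stronger of 2 equal sets of peaks (7.97) or among genes without a divergent neighbour (9.51; adjusted Fisher's exact p = 0.089, 0.261 and 0.561). Of ZAD zinc finger genes, the family of grau, 15 of 28 had a peak, or 53.6% (adjusted Fisher's exact p = 0.0421), led by trem (signal 5538.3), CG1792 (3401.5), M1BP (2476.3) and D19B (1264.5). Of genes for insulator and promoter architecture proteins, 12 of 20 had a peak (adjusted Fisher's exact p = 0.0277). Their highest peaks were at ph-p, a Polycomb group gene (8452.3), Chro (7979.4) and Cp190 (5135.5). M1BP, ZIPIC, dwg and pita are in both lists, so these calls are not independent. The ZAD call was lost in the stronger (16.7 percentage points) and weaker (1.96) of 2 equal sets of peaks and the insulator call in the weaker (9.11). Among genes without a divergent neighbour the ZAD and insulator differences were 19.1 and 17.9 percentage points (adjusted Fisher's exact p = 0.185 and 0.409). Among divergent genes they were 18.0 and 25.3 (adjusted Fisher's exact p = 0.561 and 0.286). Both calls were lost at a distance of 1000 bp, where the differences were 17.1 and 23.6 percentage points, and the insulator difference rose from 27.9 to 44.3 without replicate 1.

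Chemoreceptor, cuticle protein, eggshell and histone genes had promoter peaks less often than other protein-coding genes. Against random placement, of these lists only the chemoreceptor genes passed the test (7.14% after shifting, two-sided permutation p = 0.004). Shifting gave 7.10% for cuticle protein, 7.38% for eggshell and 6.91% for histone genes, each above the list's share, without passing that test (two-sided permutation p = 0.745, 0.597 and 0.246). Eggshell and histone genes had a share of 0, the lowest possible, and the central 95% range of their shifts also reached 0. That test could therefore not have called them below random placement. Chemoreceptor genes had 2 of 179, or 1.12%, against 32.5% of other genes (adjusted Fisher's exact p = 5.72e-26), namely Ir60e and Gr63a. Cuticle protein genes had 5 of 95, or 5.26% (adjusted Fisher's exact p = 1.07e-09). Eggshell and yolk genes had 0 of 18 (adjusted Fisher's exact p = 0.00479), an interval that reaches up to 18.5%. Replication-dependent histone genes had 0 of 111, which allows up to 3.27% (adjusted Fisher's exact p = 1.80e-18), but these are near-identical tandem copies, and how reads with several matches were treated was not given in the sources used here. Embryonic patterning genes had 9 of 43, or 20.9%, among them bcd and Dfd, germline and piRNA pathway genes 9 of 34, led by cuff (signal 6528.3), muscle marker genes 7 of 22, led by Msp300 (2894.3), and neuronal marker genes 3 of 20, led by elav (5111.8). None of these 4 lists passed the test (adjusted Fisher's exact p = 0.182, 0.622, 1 and 0.182). The patterning list passed it without replicate 2, with a difference of -16.8 percentage points, and the muscle difference of -0.28 turned to 1.04 without replicate 1 and 1.12 without replicate 2. Against shifts, tRNA genes had 36 of 290, or 12.4%, against 6.57% (two-sided permutation p = 0.01), and snRNA genes 8 of 32, against 6.81% (two-sided permutation p = 0.006). The tRNA excess of 5.85 percentage points was 12.02 without replicate 3, and the calls were lost at 250 bp for tRNA genes (2.84) and at 1000 bp for snRNA genes (18.5). Shifts are a low bar, since germline genes also exceeded them (26.5% against 8.68%, two-sided permutation p = 0.006), and the tRNA share was close to the 11.6% of all ncRNA genes, 378 of 3261.

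**Figure D3:**
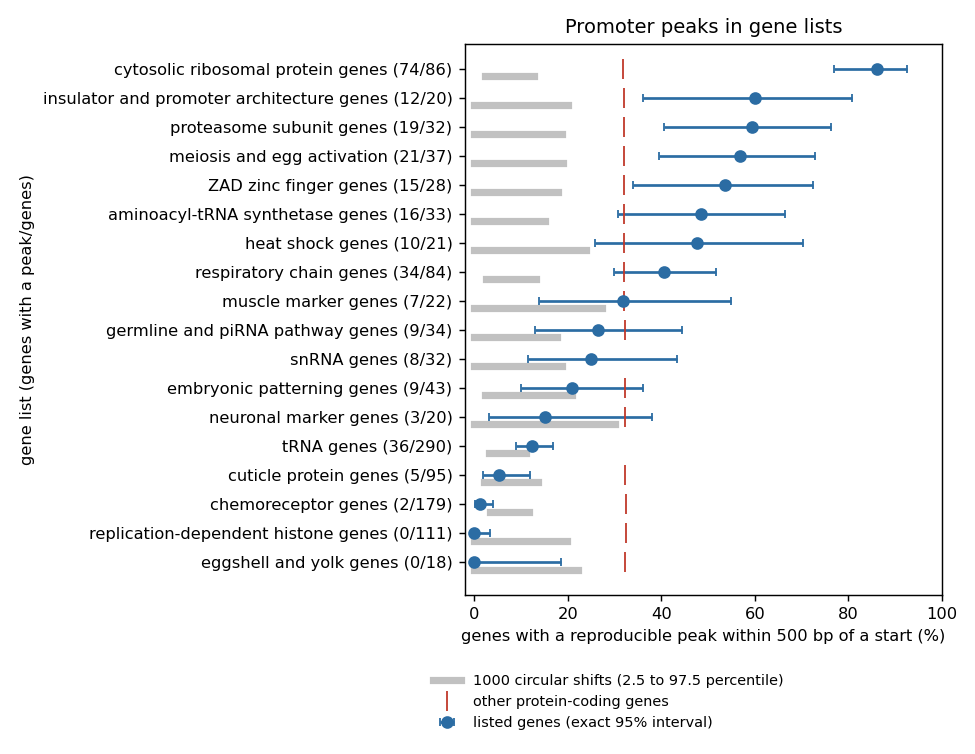
Share of each list's genes with a reproducible peak within 500 bp of a start (x axis, %), with exact 95% intervals, the central 95% range of 1000 circular shifts (grey bars) and the other protein-coding genes (red marks). Cytosolic ribosomal protein genes stand at 86.0% and chemoreceptor genes at 1.12%.

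Point sources sat in short AT-rich stretches. The GC content of the 101 bp around them was 33.3% against 43.5% in the flanks, and 29.4% in the 1000 strongest peaks, where 85.3% of peaks were below their flank. In the replicates' own 1000 strongest peaks it was 29.6% ± 0.730 (SD, n = 3). In 4 sets of 2406 peaks by signal, the GC content was 29.97%, 32.9%, 34.4% and 36.0% from the strongest to the weakest.

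**Figure D4:**
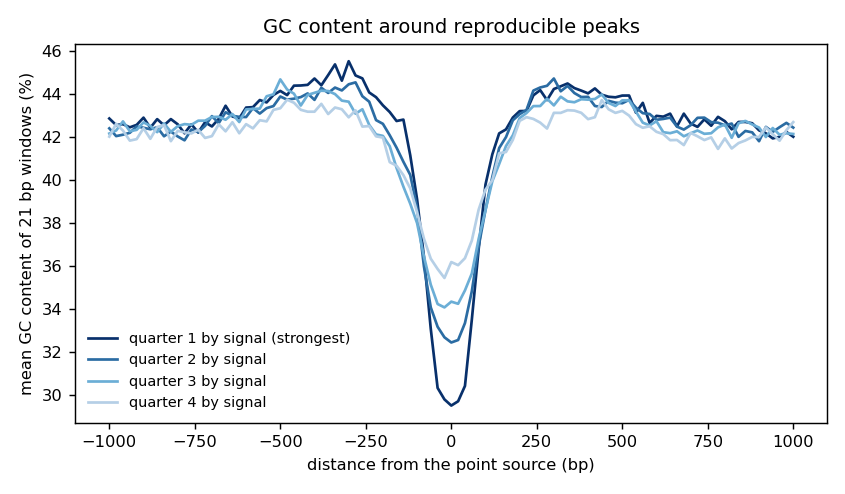
Mean GC content (y axis, %) by distance from the point source (x axis, bp) for 4 sets of 2406 reproducible peaks by signal. The 101 bp windows at the point source average 29.97% in the strongest set and 36.0% in the weakest.

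Of the 11 motifs, 9 differed between point sources and flanks. The TATA box word TATAAAA was in 10.7% of peaks against 4.03% of flanks (adjusted exact binomial p = 5.04e-70), but in dinucleotide shuffles of the same windows the difference was 0.156 percentage points and was not past the threshold. Core promoter and insulator words were rarer. The DREF and BEAF-32 word TATCGATA was in 1.68% against 0.260%, the M1BP word GGTCACACT in 0.842% against 0.125%, the CTCF core AGRKGGCGC in 1.26% against 0.281%, and the su(Hw) core TGCATAYTT in 1.07% against 0.395% (adjusted exact binomial p = 4.97e-25, 2.16e-13, 7.63e-15 and 5.06e-08). Motif 6 was in 2.39% against 1.36% and motif 7 in 1.34% against 0.592%. The DREF, M1BP and motif 7 words were not past the threshold outside promoters. The E-box CAGCTG, at 3.20% against 4.77%, and the GAGA word, at 1.04% against 2.51%, were rarer at point sources (adjusted exact binomial p = 5.06e-08 and 1.56e-14), and both were more frequent than in shuffles of the same AT-rich windows. The Zelda word and the Twist E-box did not pass the test (adjusted exact binomial p = 0.285 and 0.104). The Zelda word did pass without replicate 2, at -0.291 percentage points, and in peaks matched in all 3 lists, at -0.27. The word found on chromosome 2, ATCGATAG, which overlaps the DREF word, was in 1.57% of peaks on chromosomes 3, 4 and X against 0.243% of flanks (exact binomial p = 3.30e-16). The search in the other direction gave another word, TTCTTAAA, in 2.11% of peaks on chromosome 2 against 0.608% of flanks (exact binomial p = 6.65e-08), but also in 1.97% of shuffles of the same windows (exact binomial p = 0.727).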

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

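Of 482 comparisons of 49 results with an alternative, 44 used the top of the pooled list, which is the reproducible list and could move nothing. Of 405 others with a test, 344 kept direction and side of the threshold, 28 lost the call, 13 gained one and 20 turned. Among values without a test, 7 moved, and the number of motifs past the threshold ran from 6 to 10 and of gene lists from 6 to 12, against 9 for each. Local shifts, the most upstream start, protein-coding divergent pairs and other peak sets for cort and grau were chosen after seeing the data. The cause of the changes was not tested. The sets of stronger and weaker peaks hold fewer peaks by construction. Promoter share (33.5% to 53.8%) and divergent promoters (differences of 10.9 to 34.5 percentage points) passed under every alternative run. Promoter signal lost its call at 250 bp (ratio 1.04) and ran from 1.04 to 1.26 without single replicates. The rank correlation moved to 0.726 with any overlap, 0.770 with overlap of at least 50% of both intervals and 0.882 within 50 bp. The nearest peak to cort lay 2758 bp away in peaks matched in all 3 lists, and 25 to 2782 bp without single replicates. For grau that range was 4 to 5635 bp.

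Among features, the stronger peaks lost the 5′ UTR (0.561%) and other exon calls (0.935%), and local shifts the other exon call (1.02%), which ran from 0.966% to 1.07% without single replicates. Introns turned in peaks matched in all lists (40.6%) and ran from 37.6% to 40.3% without single replicates. For motifs, in percentage points, peaks outside promoters lost the DREF (0.0728), M1BP (0.164) and motif 7 words (0.218), and the weaker peaks lost CAGCTG (-0.561). Shuffles turned CAGCTG (2.02), GAGA (0.613) and Zelda (0.125), ended TATA (0.156) and made the Twist call (0.592). Zelda turned in the weaker peaks (0.0623) and in 25 bp windows (0.0416), passed in peaks matched in all lists (-0.27) and ran from -0.291 to -0.0935 without single replicates. Twist turned in 25 bp windows (-0.0727).

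For gene lists, in percentage points, the stronger peaks lost meiosis (7.97), ZAD (16.7), proteasome (9.06), eggshell (-19.1), tRNA (2.80) and snRNA (9.01), gained synthetase (20.4) and patterning (-14.5) and turned germline (4.46). The weaker peaks lost ZAD (1.96), insulator (9.11), eggshell (-15.9), tRNA (3.17) and snRNA (8.94), and turned synthetase (-3.79), patterning (0.382) and muscle (6.84). A distance of 250 bp lost meiosis (14.3) and tRNA (2.84). A distance of 1000 bp lost ZAD (17.1), insulator (23.6) and snRNA (18.5) and turned germline (7.66) and muscle (4.44). Merging genes that share a peak gained respiratory (15.3), synthetase (23.3) and heat shock (22.4) and turned germline (1.18) and muscle (6.54). Only genes with a peak can be merged, which lowers the share of other genes by construction. These gains and turns, which are in the counts above, are therefore no evidence about the lists. The most upstream start gained respiratory (11.01). Peaks matched in all lists gained respiratory (13.8) and turned germline (2.06). Without single replicates, respiratory ran from 10.95 to 16.9, patterning from -16.8 to -9.998 and muscle from -5.96 to 1.12. With no change of call, insulator went from 27.9 to 44.3 without replicate 1, tRNA from 5.85 to 12.02 without replicate 3, and, without replicate 2, synthetase from 16.4 to 8.72, heat shock from 15.5 to 7.41, germline from -5.64 to -1.29 and the Twist word from 0.447 to 0.27.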

Other observations

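The tests here were chosen only after the result was seen, except that of ribosomal protein genes without a divergent neighbour. With 1 group, no explanation by a difference between groups was tested.

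Mitochondrial ribosomal protein genes also stood above other genes. They were chosen because mRpS23 and mRpS10 lay at some of the strongest peaks, and 46 of 73 had a promoter peak, or 63.0% (95% interval 50.9% to 74.0%), against 31.9% of other protein-coding genes. Without those genes it was 44 of 71, or 62.0% (Fisher's exact test, adjusted over 17 tests, p = 9.15e-07). This list was not split by divergent neighbours, so a part played by shared promoters was not tested for it.

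The strongest point sources lay in AT-rich dips. If any such dip were recovered as a peak, most places with the same dip, flanks and feature class would hold one, but 11.94% of 5000 such places did (95% interval 11.1% to 12.9%), against 4.50% of random places. A first draw kept away from every reproducible peak, which made a low share certain, so the draw was repeated leaving out only the surroundings of the 1000 strongest peaks. The pooled list held exactly 30000 peaks, and the number of such places in the genome was not counted. Most of them may therefore have been unable to hold a peak. The share does not decide whether such dips favour recovery, and it was above that of random places. Places matched on feature class and distance to a start had a GC content 10.37 percentage points higher than the point sources (95% interval 9.77 to 10.96, by bootstrap), which argues against the composition of such places as the whole cause. Whether fragments of low GC content were recovered better during library preparation was not tested.

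The weak ends of the replicates' lists matched poorly. Peaks with a q-value above 0.01 matched in another replicate's list at 28.31% (25.9% to 31.6% over 6 ordered pairs), and peaks with a q-value of 0.01 or less at 75.02% (70.1% to 78.5%). This split restates the fall with rank, since at least 99.96% of the strongest peaks by signal, taken in the same number, had a q-value of 0.01 or less, so it decides nothing about lists of a fixed length that run past their q threshold. Counting any overlap by 1 bp raised the weak peaks to 55.62% (51.2% to 61.7%), but it also raised their match after shifting, from 4.55% to 15.5%. The wider match takes in separate neighbouring peaks too, so the rise cannot be read as point sources that move within a peak, and both explanations stay open.

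Ribosomal protein genes exceeded other genes beyond what shared divergent promoters give. Among genes with no start on the other strand nearby, 39 of 49 had a promoter peak, 57.80 percentage points above other such genes. Promoters shared with a start within 500 bp on the other strand therefore do not account for the excess. Starts farther apart or on the same strand can still share a peak, and their part was not tested. Among such genes the meiosis, ZAD, insulator and proteasome lists, with 10 to 19 genes each, did not pass the test, at differences of 9.51, 19.1, 17.9 and 23.4 percentage points against 24.7, 21.5, 27.9 and 27.3 over all genes (adjusted Fisher's exact p = 0.561, 0.185, 0.409 and 0.185). Among divergent genes the differences were 28.7, 17.996, 25.3 and 11.9 (adjusted Fisher's exact p = 0.0568, 0.561, 0.286 and 0.561), so with these few genes a part played by shared promoters in those lists stays open. Recovery that rises with transcription stays open: the promoter peaks of ribosomal protein genes had a median signal percentile of 61.4 among promoter peaks (95% interval 54.0 to 67.9), between the bounds set for and against it, and no expression data were used here.

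Some strong peaks of single replicates were missing from the pooled list. Of the 3000 strongest peaks of replicates 1, 2 and 3, 9, 18 and 28 lay farther than 500 bp from any pooled peak, or 0.3%, 0.6% and 0.933%. Of the 3000 strongest peaks matched in all 3 replicate lists, 5 did, or 0.167% (95% interval 0.0712% to 0.39%). The grau promoter peak of replicates 1 and 2 is in none of these sets, as it ranked 3630 and 3715 and was absent from replicate 3.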
